A study of Mus musculus with 8 samples.

How the data were processed

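Transcripts were counted in 8 libraries from mouse kidney, 5 from control mice and 3 from mice labelled Lats1/2 knockout. All mice carried the RiboTag allele and a tamoxifen-inducible Pdgfrb-Cre, and per the labels' protocols received 2 mg of tamoxifen. Libraries were made with QuantSeq, which reads the 3′ ends of transcripts. The labels give the molecule as total RNA and do not describe how tagged ribosomes were isolated, nor whether each library came from 1 animal, so p-values measure the spread between these libraries, part of which may be technical.

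The read counts per gene row are raw counts as the authors deposited them, per the file headers. The submitters' processing notes name Bowtie2, edgeR and the mm10 genome build, without versions. The counting program, its strand setting and its treatment of reads that map to several places are not stated there. The deposited fold change is headed test over con, taken as knockout over control, and the headers do not give how it was computed. Wdr19, with 0 knockout reads, has a deposited fold of 0.011, so the fold is not a plain ratio of mean counts. The deposited p-value is headed p-value for the same contrast, is given to the third decimal and is taken as unadjusted. Another 8 columns of per-sample normalised values were not used.

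The count columns of controls 3 to 5 and of knockouts 1 to 3 carry the sample titles. The other 2 count columns are headed WT1 and WT2; they were taken as control libraries by their header and tied to no particular sample. Starts equalled a GENCODE vM21 transcript start of the same gene in 10539 of 22170 symbol-matched rows as given and in 660 rows when shifted by 1 base, so coordinates are taken as 1-based on mm10. The table held 23282 gene rows, 79 of them with a repeated symbol, which were kept apart by their transcript. In 36 rows with a mean of at least 10 reads, all 8 counts equalled those of another row, so some reads were counted for several features; Wdr89 and Rplp2-ps1 held similar totals of 164456 and 164371 reads. Library totals ran from 4812490 to 6500684 counts.

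The comparison was fitted with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (TMM scaling, low-count filter by group, robust option, no covariate, 2-sided) on 13150 genes that passed the filter. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are knockout over control on the log2 scale with their standard errors (SE). The SE was taken as the absolute log2 fold change over the square root of the F statistic. Where a group had a count of 0 throughout, the fitted value and its interval depend on the small count that edgeR adds. CPM are counts scaled to a library size of 1e+06 after TMM scaling. A count of 0 was given a floor of 3 counts over the group, and ratios that rest on 1 to 3 reads have an exact 95% counting interval; both cover counting error only, since reads are not independent molecules. Other settings and their effect stand in the closing part.

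In all, 25 gene lists were fixed before the data were examined, along with the comparison, its test, the rule for naming genes and the other settings to try; 24 had members to test, and no row belonged to the list of mitochondrially encoded genes. Lists were tested with camera in limma 3.58.1 (2-sided, preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 24 lists). The same test with an estimated correlation and the rotation test fry were run beside it. The rule named the 8 genes with the smallest p in each direction at a mean log2 CPM of at least 2, since none passed the threshold; Lats1, Lats2, Yap1, Wwtr1, Myc and Mycn; and the member with the smallest p of each list. This gave 45 genes, of which the report describes all but 1. Cyr61, Ankrd1, Tbrg4, Col4a2, Fn1, Gata3, Ren1 and Xist are named in the report outside that rule and were chosen after their values were seen. Lists of adipocyte, epididymis, liver, skeletal muscle, pancreas acinar, testis and brain transcripts, of imprinted and fetal growth genes and of nuclear-retained RNA were added after the data were seen.

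Alternatives were DESeq2 1.42.0 with a Wald test, upper-quartile scaling, library size alone, no low-count filter, a mean count of at least 10, limma-voom with sample quality weights, a 2-fold minimum, a threshold of 0.1, and each library left out in turn. A fit with controls 3 to 5 alone was added after the data were seen. The scripts were tested on simulated counts for the same 3 against 5 libraries and 13150 genes, in 10 simulations with 200 changed genes each. They recovered 1.77% of 2-fold, 21.9% of 4-fold and 47.7% of 16-fold changes, and called 28 of 120985 tests of unchanged genes. A simulated shift of 0.5 in the log2 values of the 54 MYC target genes was called in 10 of 10 simulations, and without a shift in 0 of 10. Simulated genes varied independently of each other, whereas the real lists had estimated correlations of up to 0.455 (cytosolic ribosomal proteins). These runs therefore do not show how often camera calls a list of correlated genes without a shift.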

Results

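Transcripts of the kidney were counted in RiboTag mice carrying a tamoxifen-inducible Pdgfrb-Cre, a recombinase active in mesangial and other perivascular cells; the labels name the material mesangial cells. RiboTag places an epitope tag on the ribosomes of the cells in which Cre has acted. There were 5 control libraries, called here WT1, WT2, 3, 4 and 5, and 3 libraries labelled Lats1/2 knockout. The control columns are headed PB-Ribo-WT1, PB-Ribo-WT2, PB-CON-3, PB-CON-4 and PB-CON-5. The labels do not say whether the differing header names mark a batch, and this was not tested. With controls 3 to 5 alone 9 lists were called, against 5 with all libraries. Lats1 and Lats2 are the kinases of the Hippo pathway that restrain the coactivators YAP and TAZ, and the series concerns active YAP/TAZ and N-MYC in mesangial cells of the diabetic kidney. None of the 8 libraries is labelled diabetic. Library totals were 6356806, 5473662, 5538760, 6252543 and 5568703 counts in the controls and 6500684, 5043688 and 4812490 in knockouts 1, 2 and 3, with reads in 12420 to 14671 genes. The ribosomal RNA precursor Rn45s took 17.8% to 23.7% of the counts. The nuclear RNA Malat1 took 9.03%, 2.34%, 5.71%, 9.67% and 3.49% in the controls and 1.56%, 2.64% and 6.37% in the knockouts. Spearman correlations between libraries were 0.769 to 0.804 over the 10 control pairs, 0.739 to 0.778 over the 3 knockout pairs and 0.750 to 0.786 over the 15 pairs across groups.

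The comparison asked how transcripts of Pdgfrb-lineage kidney cells differ when Lats1 and Lats2 are deleted. Transcripts of both targeted genes were read in all 3 libraries labelled knockout. Lats1 (NM_010690, chromosome 10, 7681209 to 7716461 of mm10) was at 70.7, 42.2 and 20.5 CPM in knockouts 1, 2 and 3, a mean of 44.5 ± 25.2 CPM (SD, n = 3). In the controls it was at 16.1 ± 15.7 CPM (SD, n = 5), from 0.178 CPM in control 5, which is 1 read, to 41.2 CPM in control WT2. Lats2 (NM_015771, chromosome 14, 57689662 to 57746123) was at 38.7, 68.0 and 58.6 CPM in the knockouts and at 45.7 ± 45.0 CPM (SD, n = 5) in the controls, from 1.64 CPM in control 4 to 114 CPM in control WT1. The log2 fold changes were 1.46 (SE 0.92) for Lats1 and 0.27 (SE 0.93) for Lats2, with an adjusted p of 1.00 for both by edgeR's quasi-likelihood test. Without control 4 the value for Lats2 was -0.077. The deleted exons are not given in the labels, and a 3′ tag outside the deleted part is read from a deleted allele too, so these values may check neither the deletion nor the labels.

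Mean transcript levels of the coactivators themselves lay close together in both groups. Yap1 was at 87.7 ± 16.8 CPM in the controls (SD, n = 5) and 89.4 ± 24.2 CPM in the libraries labelled knockout (SD, n = 3), and Wwtr1, which encodes TAZ, at 47.7 ± 24.0 and 46.1 ± 34.9 CPM, from 6.56 CPM in control 4 to 86.1 CPM in knockout 1. Mycn, which encodes N-MYC, was read at 4.63, 9.18 and 12.6 CPM in controls 3, 4 and 5, at 0.337 and 0 CPM in controls WT1 and WT2, and at 0, 0 and 0.628 CPM in knockouts 1, 2 and 3. Pooled, these are 155 control reads against 3 knockout reads of Mycn, a ratio of 0.0351 with an exact 95% counting interval of 0.00715 to 0.104, which leaves out the spread between libraries. Against that spread its log2 fold change of -4.57 had an SE of 2.69, and its adjusted p by edgeR was 1.00. Myc was at 5.43 ± 5.12 CPM in the controls (SD, n = 5) and 8.83 ± 10.2 CPM in the knockouts (SD, n = 3), with no read in control WT2 and knockout 1.

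**Figure D1:**
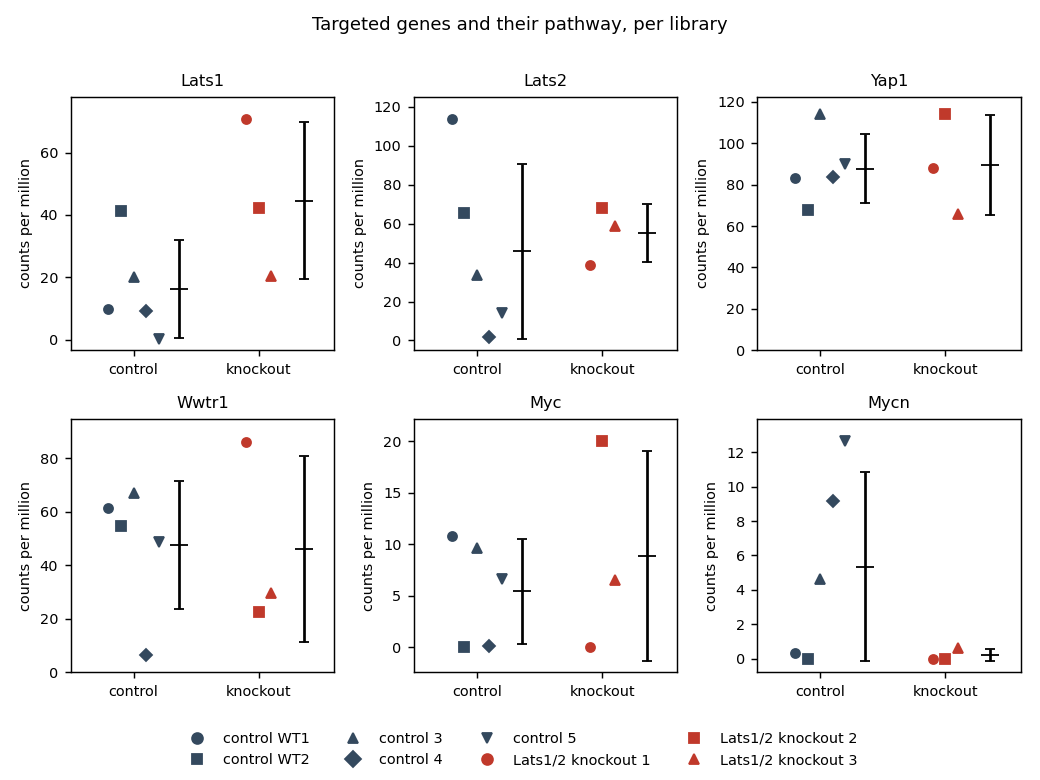
CPM of Lats1, Lats2, Yap1, Wwtr1, Myc and Mycn in each library (linear axes; symbols stand for single libraries, and the bar beside each group gives its mean and SD, n = 5 controls and n = 3 knockouts). Yap1 means are 87.7 and 89.4 CPM, and Lats1 runs from 0.178 to 41.2 CPM in the controls and from 20.5 to 70.7 CPM in the knockouts.

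No gene passed the threshold for a difference between the groups. The genes with the smallest p that were higher in the libraries labelled knockout included Gas5, a non-coding host of small nucleolar RNAs, at 337 ± 32.5 CPM in the controls and 559 ± 43.0 CPM in the knockouts. Others were the SWI/SNF subunit Smarcc1 (168 ± 41.4 and 320 ± 35.9 CPM), the cytosolic chaperone Hsp90ab1 (4893 ± 604 and 7008 ± 801 CPM) and the nonsense-mediated decay factor Upf3b (292 ± 89.0 and 599 ± 204 CPM; SD, n = 5 and n = 3 throughout). Zc3h6, Ifrd2 and the vacuolar ATPase subunit Atp6v0a2 were also on this side, with log2 fold changes of 1.96 (SE 0.48), 1.86 (SE 0.47) and 1.68 (SE 0.46). In each of these genes every knockout value lay above every control value. They were chosen for their small p, which favours such a separation, so it lends them no further weight.

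On the lower side stood Dusp1, a phosphatase that inactivates MAP kinases, at 90.8 ± 20.4 CPM in the controls and 37.0 ± 9.13 CPM in the knockouts. Fam126b (96.6 ± 21.5 and 39.3 ± 7.51 CPM), Wfdc15b (68.5 ± 21.1 and 20.1 ± 8.38 CPM), the lens crystallin Crygc (53.4 ± 29.1 and 9.57 ± 5.20 CPM) and the retrotransposon-derived Rgag4 (47.7 ± 29.8 and 6.18 ± 4.50 CPM) stood beside it. Cdkl1, a kinase related to the cyclin-dependent kinases, had 766 reads over the controls and 1 over the knockouts, in knockout 1. This is a ratio of 0.00236 (exact 95% counting interval 5.98e-05 to 0.0132). The prostaglandin D synthase Ptgds had 520 and 3 reads, a ratio of 0.0105 (0.00215 to 0.0307). All 3 were in knockout 1, and 241 of the control reads were in control 3. Wdr19, an intraflagellar transport gene, had 466 and 0 reads, at least 85.7-fold lower against a floor of 3 counts over the group. These counting intervals and this floor leave out the spread between libraries. With it, the unadjusted 95% intervals of the fitted log2 fold change were -11.5 to -5.18 for Cdkl1, -10.2 to -2.89 for Ptgds and -14.0 to -5.00 for Wdr19. As Wdr19 had 0 knockout reads, both ends of its interval depend on the small count that edgeR adds and do not measure the fold. The 3′ end of Rgag4 lies over Nhsl2 on the opposite strand, and their reads cannot be told apart where the strand setting is not stated; that of Gas5 lies over Snord47 on the same strand.

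By edgeR's quasi-likelihood test, 0 of 13150 genes had an adjusted p under 0.05; the smallest was 0.556, for Cdkl1, and the other genes named here were at 1.00. At an unadjusted p under 0.05 there were 547 genes, 178 higher and 369 lower, where 657.5 would be met with no effect. DESeq2 called 60 genes, 4 higher and 56 lower (693 at an unadjusted p under 0.05); 30 of them had no read in any knockout library, and 8 are named in this report: Cdkl1, Wdr19, Gas5, Crygc, Wfdc15b, Rgag4, Ptgds and Bambi. Limma-voom with sample quality weights called 0 genes (729 at an unadjusted p under 0.05). Without knockout 1, edgeR called 16 genes, all lower, of which Fabp4 and Lpl are adipocyte transcripts and 7 belong to the liver list, among them Mup1 and Trf. In 528 genes, 4.01% of those tested, the groups did not overlap, where chance gives 3.57%. The fit's biological coefficient of variation was 0.964.

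Known target genes of YAP and TAZ were not called as a list. Of 19 tested members, 4 were higher and 15 lower in the libraries labelled knockout, with a median log2 fold change of -0.41 and a mean of -0.18 (camera adjusted p = 0.95). With controls 3 to 5 alone the median was 0.046. Ctgf, a widely used readout of the pathway, was at 232 ± 93.4 CPM in the controls and 375 ± 194 CPM in the knockouts (SD, n = 5 and n = 3), while Cyr61 had a log2 fold change of -0.56 (SE 0.51) and Ankrd1 one of 1.14 (SE 1.25). Over the 21 tested components of the Hippo pathway the median was -0.09 and the mean -0.10, although camera's direction was up (adjusted p = 0.993). The component with the smallest p was Frmd6, an upstream activator of the pathway, at 42.0 ± 15 and 16.9 ± 9.09 CPM. None of the members of either list passed the threshold, whether over all genes or adjusted over the list alone.

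MYC target genes, which serve mainly in ribosome assembly and nucleolar function, rose as a list. Of 54 members, 36 were higher and 18 lower, with a median log2 fold change of 0.33 and a mean of 0.17 (camera adjusted p = 0.00223). The call was lost when the correlation was taken from the data (adjusted p = 0.648 with an estimated correlation), and the adjusted p was 0.122 without knockout 2. Npm1, a nucleolar chaperone, was at 426 ± 85.4 CPM in the controls and 606 ± 92.3 CPM in the knockouts (SD, n = 5 and n = 3), and Tbrg4 had a log2 fold change of 1.17 (SE 0.51). Of the 14 members of the MYC family and their partners, 10 were higher, with a median of 0.34 (adjusted p = 0.156, and 0.0249 without control 3 or 0.0336 without knockout 1). Mxi1, an antagonist of MYC, was at 22.9 ± 6.75 and 46.1 ± 16.9 CPM. No member of either list passed over all genes or adjusted over the list alone.

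Genes of the cytosolic ribosomal proteins rose as a list by a small amount. Of 79 members, 67 were higher, with a median log2 fold change of 0.18 (camera adjusted p = 2.1e-05; adjusted p = 0.849 with an estimated correlation; 0.122 without knockout 2). Rps20 was at 1752 ± 352 CPM in the controls and 2663 ± 101 CPM in the knockouts (SD, n = 5 and n = 3). Summed over the list, the lowest values were 27230 CPM in control WT1 and 33060 CPM in control 4, the libraries with the highest Malat1 shares, and the highest was 44710 CPM in knockout 2. Of these 79 genes 0 passed over all genes and 0 adjusted over the list alone.

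Extracellular matrix genes also rose as a list. Of 40 members, 30 were higher, with a median log2 fold change of 0.27 and a mean of 0.29 (camera adjusted p = 0.00371; adjusted p = 0.164 with an estimated correlation; 0.0587 without knockout 3). The estimated correlation of this list was -7.4e-05, under the preset 0.01, so correlated members do not account for the lost call. Summed over the list, knockouts 1, 2 and 3 were at 5214, 4987 and 5086 CPM, and the controls ran from 3955 to 4792 CPM. Col15a1, a collagen of basement membrane zones, was at 58.2 ± 19.2 CPM in the controls and 110 ± 15.4 CPM in the knockouts (SD, n = 5 and n = 3). The basement membrane collagen Col4a2 had a log2 fold change of 0.60 (SE 0.29) and fibronectin, Fn1, one of 0.59 (SE 0.29). No member passed over all genes or adjusted over the list alone.

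No difference in mesangial markers was detected. Over 16 tested members, 8 were higher and 8 lower, with a median log2 fold change of 0.05 (adjusted p = 0.993). Pdgfrb, whose promoter drives the Cre, was at 122 ± 66.0 CPM in the controls and 78.8 ± 32.5 CPM in the knockouts (SD, n = 5 and n = 3), and Gata3 had a log2 fold change of -0.52 (SE 0.45). Summed mesangial markers were at 2896 CPM in control WT1 and between 943 and 1393 CPM in the other libraries. Among smooth muscle and contractile genes 15 of 22 were higher (median 0.10, adjusted p = 0.168), and the actin-binding Cald1 was at 477 ± 170 and 887 ± 232 CPM. Of 29 cell cycle genes 18 were higher (median 0.22, adjusted p = 0.168), and the ribonucleotide reductase subunit Rrm1 was at 24.8 ± 8.85 and 50.3 ± 19.6 CPM. Over all genes, and adjusted over the list alone, 0 members of these 3 lists passed.

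**Figure D2:**
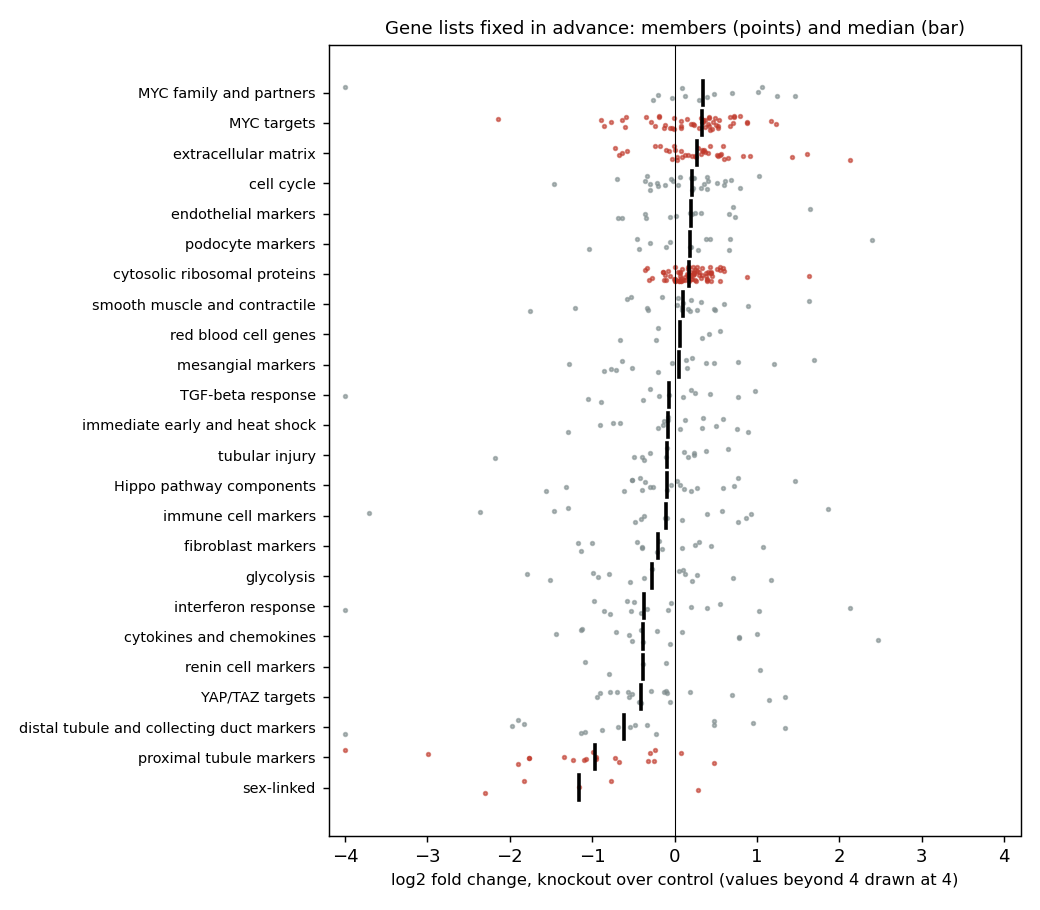
Log2 fold change, knockout over control, of each member (points) and the median (black bar) of the 24 gene lists; values beyond 4 are drawn at 4, and red marks the 5 lists with an adjusted p under 0.05 at the preset correlation, all of them lost with an estimated correlation. Medians run from -1.16 for sex-linked genes to 0.34 for the MYC family and partners.

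Markers of other kidney cells were read in every library, and those of the proximal tubule fell as a list. Of its 20 members, 18 were lower, with a median log2 fold change of -0.97 and a mean of -1.36 (camera adjusted p = 7.9e-04). The camera adjusted p was 0.695 with an estimated correlation, 0.124 without control 4 and 0.122 without knockout 2. Over the alternatives the median ran from -2.06 to -0.51, the latter without control 4. Slc5a12, a lactate transporter of the proximal tubule, was at 332 CPM in control 4, from 64.3 to 124 CPM in the other controls and from 22.2 to 55.5 CPM in the knockouts. Summed proximal tubule markers were at 5657 CPM in control 4, whose Malat1 share of 9.67% was the highest, and at 993, 918 and 3006 CPM in knockouts 1, 2 and 3; knockout 3 lay above 4 of the 5 controls. Distal tubule and collecting duct markers had 12 of 16 members lower (median -0.62, adjusted p = 0.156, 0.0154 with DESeq2 and 0.00939 with controls 3 to 5 alone; the median was -0.026 without knockout 1), and the kinase Wnk1 was at 695 ± 238 and 431 ± 142 CPM (SD, n = 5 and n = 3). Podocyte markers had a median of 0.19 over 14 genes (adjusted p = 0.175, 0.0103 without control WT1 and 6.0e-05 with controls 3 to 5 alone; the median was -0.10 without control 4 and -0.47 without knockout 3), with Ptpro at 43.0 ± 32.6 and 68.7 ± 20.6 CPM. Endothelial markers had a median of 0.20 over 14 genes (adjusted p = 0.170), with Egfl7 at 155 ± 53.3 and 253 ± 30.2 CPM. Their adjusted p was 0.0229 without control WT1 and 0.00600 with controls 3 to 5 alone, and their median -0.00865 without control 4. With an estimated correlation over all 8 libraries, camera gave an adjusted p of 0.849 for distal, 0.992 for podocyte and 0.927 for endothelial markers. The settings that called these lists were not run with an estimated correlation.

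Fibroblast markers had a median of -0.20 (14 genes, adjusted p = 0.832), with the non-coding RNA Meg3 at 2712 ± 363 CPM in the controls and 3328 ± 649 CPM in the knockouts (SD, n = 5 and n = 3). Markers of renin cells had a median of -0.38 over 5 genes and a mean of -0.27, although camera's direction was up (adjusted p = 0.993; the median was 0.84 with controls 3 to 5 alone); Akr1b7 was at 2103 ± 1328 and 1217 ± 808 CPM and Ren1 had a log2 fold change of 1.04 (SE 1.28). Immune cell markers had a median of -0.10 (16 genes, adjusted p = 0.832), with Tyrobp at 11.8 ± 9.48 and 0.874 ± 0.801 CPM. Red blood cell genes had a median of 0.06 (6 genes, adjusted p = 0.993), with Hbb-bs, a near copy of other beta-globin genes that could share its reads, at 233 ± 67.7 and 311 ± 86.1 CPM. The 5 sex-linked genes fell as a list (median -1.16, adjusted p = 0.0205; adjusted p = 0.672 with an estimated correlation; 0.118 without control 4 and 0.570 without knockout 2). Ddx3y on the Y chromosome was at 75.9 ± 16.1 and 44.6 ± 12.0 CPM, and Xist, transcribed from the inactive X chromosome of females, at 770 ± 900 and 345 ± 122 CPM, with reads of both in all 8 libraries. Xist was at 2198 and 1133 CPM in controls 4 and 5. In controls WT1, WT2 and 3 it was at 192, 179 and 147 CPM, below the 414, 417 and 205 CPM of the knockouts. Mean log2 CPM over the sex-linked list was 1.965 in knockout 2 and from 4.491 to 6.079 in the other libraries. The list joins Xist to Y-linked genes, so its direction does not tell the mix of sexes. No member of these 9 lists passed over all genes or adjusted over the list alone.

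**Figure D3:**
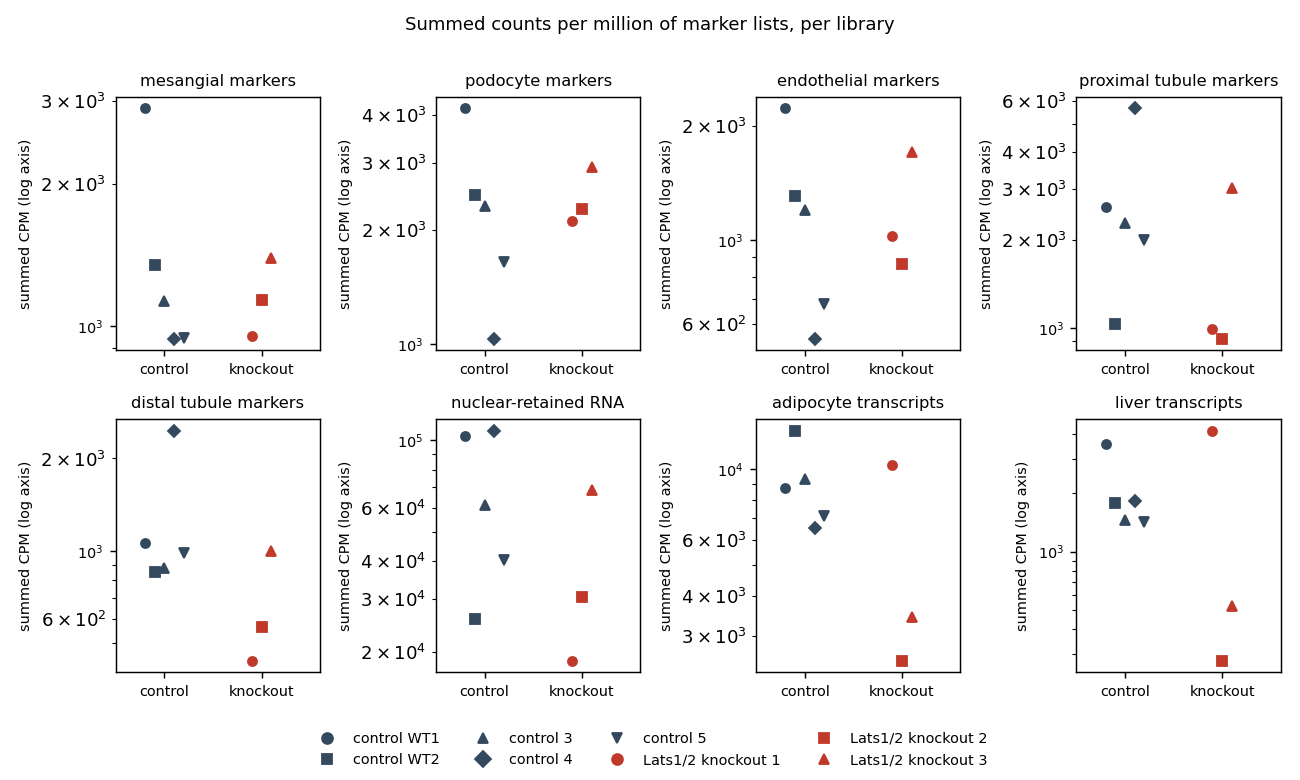
Summed CPM (log axes) of 8 marker lists in each library, with symbols for single libraries (5 controls, 3 knockouts). Proximal tubule markers run from 918 to 5657 CPM, and adipocyte transcripts are at 2503 and 3447 CPM in knockouts 2 and 3 and at 6551 CPM or more in the other libraries.

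None of the injury and signalling lists was called with all 8 libraries. Tubular injury genes had a median of -0.09 and a mean of -0.17 over 13 genes, although camera's direction was up (adjusted p = 0.993); Sox9 was at 225 ± 59.2 CPM in the controls and 294 ± 38.0 CPM in the knockouts (SD, n = 5 and n = 3). Genes of the TGF-beta response had a median of -0.07 (13 genes, adjusted p = 0.993). Bambi, a decoy receptor of that pathway, had 236 control reads, 1 of them in control WT2, and none in the knockouts. Pooled, that is at least 43.4-fold lower by counting error alone. With the spread between libraries, the unadjusted 95% interval of its fitted log2 fold change ran from -14.6 to -2.48. Cytokines and chemokines had a median of -0.38 and a mean of -0.09 over 15 genes, with camera's direction up (adjusted p = 0.993); Cxcl12 was at 82.6 ± 27.9 and 142 ± 18.1 CPM. Interferon response genes had a median of -0.37 (16 genes, adjusted p = 0.993). Gbp2 had 282 control reads, of which 183 were in control 3 and none in controls WT1 and 5, and none in the knockouts. By counting error alone Gbp2 was at least 51.9-fold lower, or 22.6-fold without control 3. With the spread between libraries, its unadjusted 95% interval ran from -15.8 to -1.74 in log2. Bambi and Gbp2 had no knockout reads, so the ends of their intervals depend on the small count that edgeR adds and do not measure the fold. Glycolysis genes had a median of -0.28 (15 genes, adjusted p = 0.692), with Gpi1 at 57.0 ± 16.6 and 93.3 ± 40.3 CPM. Immediate early and heat shock genes had a median of -0.08 and a mean of -0.04 over 17 genes, with camera's direction up (adjusted p = 0.862), but with controls 3 to 5 alone they rose as a list (median 0.45, adjusted p = 0.0181); adjusted over the list alone, Dusp1 was the 1 member that passed (adjusted p = 0.0314). Over all genes 0 members of these 6 lists passed, and adjusted over the list alone 0 members of the other 5.

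The authors' table gives a p under 0.05 to 740 genes, of which 428 had a fold of at least 2 in either direction, 244 higher and 184 lower in the libraries labelled knockout. Of the 740, 681 were among the 13150 genes tested here, where 657.5 would be met with no effect, and 255 also had an unadjusted p under 0.05 by edgeR. In the authors' table Lats1 had a fold of 2.73 (p = 0.090), Lats2 of 1.20 (p = 0.746) and Mycn of 0.071 (p = 0.171).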

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

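All tests of explanations in this part, the regroupings of the libraries included, were chosen or written down after the results were seen. The outlying values concern the 5 controls, of which 73 sets of values were looked at; 5 sets had a library far from the others, and chance gives about 1 in 20. Gas5 was at 394 CPM in control 3 and at 316 to 327 CPM in the other controls. Wdr19 was at 35.4 CPM in control WT1. Slc5a12 was at 332 CPM in control 4. Summed mesangial markers stood at 2896 CPM in control WT1. Summed distal tubule and collecting duct markers stood at 2467 CPM in control 4.

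The wide spread between libraries of one group comes with 0 called genes, although the median coefficient of variation among controls was 0.191 for genes at 500 CPM or more and 0.747 at 5 to 20 CPM. A difference in library size is argued against, since the largest total was 1.35 times the smallest. Few RNA molecules behind the reads remain a candidate explanation: the squared variation beyond counting error was 14.9 times larger at 5 to 20 CPM than at 500 CPM or more, where 10 had been set as the bound, and 44 of 6892 genes at a control mean of at least 20 CPM had no read in at least 1 control. Among these genes are Lcn5 and Lcn9 of the epididymis list, with control means of 132 and 34.3 CPM and no read in control WT2. Other tissue in differing amounts could also leave genes without reads, which was not tested. In 11 of 56 splits of the 8 libraries into 5 and 3 at least 547 genes had an unadjusted p under 0.05 (highest of the others 840), so chance cannot be excluded for that count, while for the 0 genes that passed the splits decide nothing, as all 56 reach 0 (highest 4). Differences between animals were not tested.

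The lower proximal tubule markers in the libraries labelled knockout may follow the amount of nuclear and tubule RNA carried into each library. Over the 8 libraries, mean log2 CPM of the proximal tubule markers followed that of Malat1, Neat1 and Kcnq1ot1 with Pearson r = 0.903 (exact permutation p = 0.00317, adjusted 0.00634 over 4 relations) and Spearman rho = 0.952 (exact permutation p = 0.00114, adjusted 0.00456), and r = 0.946 without knockout 2 and control 4, and for deviations from the group means r was 0.856 (exact permutation p within groups = 0.0208, adjusted 0.0832). With the distal markers r was 0.687 (exact permutation p = 0.0642) and rho 0.310 (exact permutation p = 0.462), r = 0.681 without the same libraries, and r = 0.608 for deviations from the group means (exact permutation p within groups = 0.165, adjusted 0.212), which leaves open whether all tubule segments moved together. As many as 14 of 56 splits gave a list p as small (real 6.6e-05, smallest of the others 3.7e-17), so chance cannot be excluded, and splits with far smaller p point to a structure of the samples. An effect of the genotype on tubule cells stays open and was not tested.

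Adipocyte transcripts were read in all 8 libraries, and adipose tissue RNA in differing amounts is a candidate source. The median correlation between the 19 tested genes over the libraries was 0.749, above the 95th percentile of 0.0925 from 10000 random lists matched on expression. The liver (0.83), proximal tubule (0.448) and imprinted and fetal growth (0.344) lists also lay above their 95th percentiles. Lists of genes that vary together pass this comparison whatever the reason, so it does not tell the source of the adipocyte transcripts. Liver transcripts followed them with Pearson r = 0.916 (exact permutation p = 0.00315, adjusted 0.00634) and Spearman rho = 0.810 (exact permutation p = 0.0218, adjusted 0.0436), but with r = 0.530 without knockouts 2 and 3 and r = 0.891 for deviations from the group means (exact permutation p within groups = 0.0986, adjusted 0.197), so that the relation rests on those libraries and 1 common source cannot be told apart from separate ones. The summed list was at 2503 and 3447 CPM in knockouts 2 and 3 but at 10260 CPM in knockout 1, against 8981 ± 2617 CPM in the controls (SD, n = 5; camera adjusted p = 1.0e-04 over the added lists; adjusted p = 0.519 with an estimated correlation), and 16 of 56 splits gave a p as small (real 1.5e-05, smallest of the others 4.8e-22), so chance cannot be excluded. An effect of the genotype, and reads exchanged between libraries that share indexes, were not tested.

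For the other lists the splits of the 8 libraries gave a camera p as small in 11 of 56 for cytosolic ribosomal proteins (real 8.8e-07, smallest of the others 6.5e-12), in 3 of 56 for MYC targets (2.8e-04 and 6.3e-05) and in 4 of 56 for sex-linked genes (0.00428 and 0.00120), so chance cannot be excluded for them. For extracellular matrix genes it was 2 of 56 (6.2e-04 and 2.6e-04), the smallest share of the 6 lists put through the splits. Of these 6, 5 were taken because they had been called among the 24 lists, and the adipocyte list was added after the data were seen. The bound makes no allowance for that choice, so chance cannot be excluded for extracellular matrix genes either. Their list was not called with an estimated correlation (adjusted p = 0.164) or fry (0.224). Before adjustment over the lists, these p-values were 0.00684 by camera and 0.00935 by fry. The estimated correlation itself was -7.4e-05, under the preset 0.01.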

How the results depend on the processing

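The settings that keep controls 3 to 5 alone, leave out the Rn45s and Malat1 counts, or use a replicate block were chosen after seeing the data; the other settings were fixed in advance. Where a value changed, the cause was not tested. Among the values of single genes and further lists, 932 recomputed values kept direction and side of the threshold, 16 passed it newly, 11 lost it and 46 reversed; among the main counts and lists these were 196, 1, 6 and 8, with 13 counts moved. No gene passed by edgeR with upper-quartile scaling, library size alone, no low-count filter, a mean count of at least 10, a 2-fold minimum, a threshold of 0.1, controls 3 to 5 alone or without the Rn45s and Malat1 counts, nor by limma-voom. DESeq2 called 60 genes, 4 higher and 56 lower. Leaving out 1 library at a time gave 0 to 16 genes, all of the 16 lower and called without knockout 1. Lats1 was at 2.18 and Lats2 at 1.75 with controls 3 to 5 alone, and at 2.13 and 1.20 with limma-voom, without passing. Leaving out 1 library, the log2 fold change ran from 0.97 (without knockout 1) to 2.17 (without control WT2) for Lats1, from -0.077 (without control 4) to 0.94 for Lats2, from -0.73 to 1.28 for Myc, from -0.20 to 0.19 for Yap1 and from -0.87 to 0.27 for Wwtr1. Yap1 was at -0.013 with a mean count of at least 10 and with limma-voom, and at -0.10 with controls 3 to 5 alone, where Wwtr1 was at 0.19. Of the 18 lists outside the 6 main ones, 3 were called; 0 were with an estimated correlation or fry, 7 with controls 3 to 5 alone (among them podocyte markers, median 0.45, endothelial markers, 0.55, and distal tubule and collecting duct markers, -0.70), and 0 (without knockout 2) to 5 (without control WT1) when 1 library was left out, with 1 called without control 4. With an estimated correlation and with fry the MYC targets (median 0.33) and extracellular matrix genes (0.27) kept their medians but were not called (adjusted p 0.648 and 0.164 with an estimated correlation, 0.590 and 0.224 with fry); these tests use the same fold changes. Leaving out 1 library, the median ran from 0.17 to 0.36 for MYC targets (not called without knockout 2, adjusted p = 0.122) and from 0.15 to 0.34 for extracellular matrix genes (not called without knockout 3, adjusted p = 0.0587). Over all 19 alternatives, 16 called each of these lists and all kept the sign. With controls 3 to 5 alone, medians reversed for YAP/TAZ targets (0.046), Hippo components (0.035), the mesangial markers list (-0.00569), renin cell markers (0.84), immune cell markers (0.022), tubular injury (0.019) and immediate early and heat shock genes (0.45, adjusted p = 0.0181, range over the alternatives 0.0181 to 0.998). With no low-count filter they reversed for mesangial markers (-0.038), tubular injury (0.013) and the TGF-beta response (0.15), and with limma-voom for the red blood cell genes list (-0.00842), tubular injury (0.14), the TGF-beta response (0.21) and immediate early and heat shock genes (0.065). Leaving out 1 library, medians that changed sign ran from -0.15 to 0.15 for mesangial markers, from -0.47 to 0.25 for podocyte markers, from -0.00865 to 0.44 for endothelial markers, from -0.43 to 0.23 for immune cell markers, from -0.18 to 0.13 for red blood cell genes, from -0.10 to 0.15 for tubular injury, from -0.26 to 0.18 for the TGF-beta response, from -0.48 to 0.13 for cytokines and chemokines, from -0.54 to 0.013 for the interferon response, from -0.40 to 0.040 for glycolysis and from -0.22 to 0.25 for immediate early and heat shock genes. The column headers of the groups share the numbers 3 and 4, which tie control 3 to knockout 1 and control 4 to knockout 2. The labels do not say what a number stands for, so the numbers were not taken as pairs. Within these 4 libraries, deviations of control 3 and knockout 1 from their group means had r = 0.0176. With 2 libraries per group the other pair gives the same r, so this value cannot decide whether the numbers mark pairs. A replicate block on these 4 libraries, with 1 residual degree of freedom, gave 1 gene, lower, where the same 4 without it gave 0, and 7 called lists either way; against all 8 libraries the YAP/TAZ targets reversed (median 0.077) and smooth muscle and contractile genes were called (0.22, adjusted p = 0.0499), while no other main list or targeted gene changed its call. A test on the authors' normalised log2 values was not run, because the WT1 and WT2 columns could be tied to the control group in 1 measure only. At this depth and spread edgeR missed most simulated 2-fold changes of single genes (1.77% recovered). It recovered 21.9% of 4-fold and 47.7% of 16-fold changes, so an uncalled gene may still differ by these amounts.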

Other observations

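The lists in this part and their tests were chosen after the data were seen. Transcripts of imprinted and fetal growth genes were read in both groups, at levels that differed widely between genes. Dlk1, a growth regulator of immature mesenchymal cells, ran from 5437 to 8773 CPM over the 8 libraries, H19 from 939 to 1425 CPM and Igf2 from 242 to 498 CPM. Summed over 15 genes the list was at 14080 ± 2154 CPM in the controls (SD, n = 5) and 16040 ± 1853 CPM in the knockouts (SD, n = 3), with a median log2 fold change of 0.20 (camera adjusted p = 0.0160; adjusted p = 0.519 with an estimated correlation). Meg3 and Cdkn1c of this list are also in the fibroblast and podocyte lists.

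Transcripts of tissues outside the kidney were read in every library. Fabp4 ran from 832 to 4376 CPM, Scd1 from 565 to 3044 CPM, Lpl from 257 to 1586 CPM and Cfd from 131 to 1511 CPM, which are abundant in adipocytes; Lpl, Scd1 and Cd36 are made by other tissues as well, and how many of the list the kidney expresses is not known here. Of liver transcripts, Trf ran from 99.5 to 1393 CPM and Alb from 41.2 to 625 CPM, and the list summed to 275 CPM in knockout 2, 526 CPM in knockout 3 and 4174 CPM in knockout 1 (camera adjusted p = 0.00583; adjusted p = 0.519 with an estimated correlation). Epididymis transcripts summed to 288 CPM in knockout 2 and to 2157 CPM in control 3, with Crisp1 from 157 to 656 CPM, Spink8 from 51.0 to 511 CPM and Adam7 from 0.40 to 442 CPM (adjusted p = 0.0218; adjusted p = 0.519 with an estimated correlation). The nuclear-retained RNAs, of which Xist is also in the sex-linked list, summed to 18710 CPM in knockout 1 and 107700 CPM in control 4 (adjusted p = 0.0218; adjusted p = 0.519 with an estimated correlation). Skeletal muscle transcripts, one of which, Pvalb, is also in the distal tubule list, summed to at most 93.2 CPM (adjusted p = 0.490), brain transcripts to at most 142 CPM (adjusted p = 0.914), pancreas acinar transcripts to at most 57.9 CPM and testis transcripts to at most 24.4 CPM. The adipocyte, liver, epididymis, pancreas acinar, testis and brain lists share no gene with a list fixed in advance.

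Genes of the cytosolic ribosomal proteins went against nuclear-retained RNA over the 8 libraries, with Pearson r = -0.693 (exact permutation p = 0.0539, adjusted 0.0642 over 4 relations), Spearman rho = -0.762 (exact permutation p = 0.0368, adjusted 0.0491), r = -0.543 without knockout 2 and control WT1, and r = -0.556 for deviations from the group means (exact permutation p within groups = 0.212).

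Xist and the Y-linked Ddx3y were read together in each library. In knockout 2 the sex-linked list summed to 448.8 CPM, of which Xist made up 417.4 CPM and Ddx3y 31.22 CPM. The other Y-linked genes of the list were thus close to absent in that library. Xist ran from 147 to 2198 CPM and Ddx3y from 31.2 to 91.4 CPM over the 8 libraries. The labels give no sex, and neither pooled animals nor reads exchanged between libraries were tested.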
